A study of Homo sapiens with 12 samples.

How the data were processed

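Poly-A selected RNA of HT-29 cells was sequenced by the authors as 100 nt paired-end reads on a HiSeq2000, from libraries made with a stranded TruSeq mRNA kit. Per the submitters' processing notes, TopHat2 2.0.13, Cufflinks 2.2.1, STAR 2.4.0f1 and GATK (no version given) were used with the hg19 genome, without a stated role or order. For each of the 4 libraries of the first experiment the authors deposited a Cufflinks transcript list with the FPKM, its interval and the coverage of every RefSeq and assembled transcript. For the 8 libraries of the second experiment they deposited 1 table of gene values; its header does not name the unit, which was taken as FPKM from the values and from the use of Cufflinks. No file held read counts, so tests that need counts were not run, and whether the authors scaled the 8 libraries further is not stated. Groups and replicate numbers came from the sample titles.

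The table of the second experiment had 29437 lines and 19128 gene symbols. Of these symbols 384 stood on more than 1 line, and 3300 lines repeated another exactly. The line with the highest mean was kept for each symbol, a choice made after the table was seen; the sum over distinct lines was run as an alternative. Genes with a mean of at least 1 FPKM in at least 1 of the 4 groups were kept (10364 genes). In the first experiment the FPKM of the RefSeq transcripts of a gene were summed, and an 89 bp entry on chromosome 1 (567705 to 567793), which took 83.3 to 89.9% of all FPKM, matched no gene name and so was left out of gene values. The reference annotation at hand was of GRCh38.p14, so it served only to match gene names (19007 of 19128 symbols), and coordinates are those of the deposited hg19 transcripts. The 13 mitochondrially encoded genes were not measured, so their share, a sign of RNA quality, is not given.

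Depth could be given only in relative terms. For genes at 0.15 FPKM or less in a pair of libraries, the commonest ratio of the values (bins of 0.01 log2) was taken as the inverse ratio of depths, because such values rest on the same few fragments. The libraries lay between 82.9 and 100.0% of the deepest. No counting interval or detection floor can be derived from these values, and the number of libraries limits the precision.

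Log2(FPKM + 1) values of the 8 libraries were fitted with limma 3.58.1 in R 4.3.3 (group means, empirical Bayes with a trend, 4 residual and 3.46 prior degrees of freedom). The 5 contrasts were TBZ against DMSO in each line, the difference of those effects, and shMLKL against shGFP under each condition. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, within a contrast. The replicate number was not a block, as no label says what it marks; residuals of replicates with the same number correlated at −0.066 to 0.028 over the 6 group pairs, below the limit of 0.1 set for a block. The procedure was tested on simulated data with 200 changed genes among 10187 in 20 runs: it recovered 77.7% at a log2 change of 0.5, 95.9% at 1, 95.4% at −1 and 99.8% at 2, with 8.7 false calls on average.

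Gene lists were fixed before the data were examined: NF-kB feedback and survival targets, chemokines, cytokines and growth factors of inflammation, AP-1 and immediate early genes, MAP kinase feedback regulators, interferon-stimulated genes, necroptosis machinery, regulators of the BCL2 and caspase families, unfolded protein and integrated stress response, heat shock and oxidative stress, p53 targets, cholesterol synthesis and uptake, cell cycle, glycolysis and hypoxia, intestinal differentiation, WNT targets and stem cell genes, ESCRT-III and membrane repair, TRIM28 corepressor complex, ribosomal proteins, replication-dependent histones, mitochondrial transcripts, and markers of leukocytes, of fibroblasts and endothelium, and of kidney and liver lines. Each was tested with camera (preset correlation 0.01, BH over the lists of a contrast), with camera at an estimated correlation and with fry. Camera sets a list against all other genes. In every called list the mean, the median and the test had the same sign. They differed in sign only for uncalled lists: necroptosis in all 5 contrasts, ESCRT-III in shGFP, in the difference of effects and under TBZ, glycolysis in shGFP and under DMSO, kidney and liver markers in both TBZ contrasts, leukocyte markers in both line contrasts, histones in shGFP, ribosomal proteins in shMLKL, NF-kB targets and BCL2 and caspase regulators under DMSO, and cell cycle and intestinal genes under TBZ. Of the fibroblast and endothelium markers fewer than 3 were measured, so that list was not tested.

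The named-gene rule was fixed before the data were examined. It took MLKL; in each contrast the 5 largest rises and 5 largest falls among called genes with at least 5 FPKM in the higher group and non-overlapping replicates; up to 3 called members of each called list, or of a list with at least 5 called members, in the TBZ contrasts; and TNFRSF1A, RIPK1, RIPK3, CASP8, CFLAR, BIRC2 and BIRC3. For the first experiment it took the genes named in the matching contrast and the 3 largest ratios in each direction. Many picks were listed at 0 in a library, which can be a missing estimate. The rule was run a second time without genes listed at 0, a step chosen after the data were seen. Of the genes picked, 2 are not reported. The first experiment had 1 library per group, so only log2 ratios with a pseudocount of 1 were computed, for genes at 1 FPKM or more in either library, and list medians were placed among 10000 random lists matched on mean expression.

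Alternatives planned before the data were examined were pseudocounts of 0.1 and 0.5, no filter and a filter of 5 FPKM, quantile normalization, library medians set equal, a replicate block, no trend, robust empirical Bayes, only the libraries compared, a threshold of 2-fold, and leaving out each library in turn; for the first experiment, pseudocounts of 0.1 and 5, a filter of 5 FPKM, the most abundant transcript and a median ratio set to 0. Those added later were leaving out genes listed at 0, the sum over distinct lines, a floor of 0.5 FPKM, assembled transcripts added to genes, and library medians set equal for the lists. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the remaining work.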

Results

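Polyadenylated RNA was sequenced from HT-29 cells, a human colorectal adenocarcinoma line, in 12 libraries of 2 experiments. TBZ stands for TNFα at 20 ng/mL, BV6 at 2 µM and zVAD-fmk at 30 µM. BV6 antagonises the inhibitor of apoptosis proteins and zVAD-fmk blocks caspases, a combination used to drive death by necroptosis. MLKL, the target of the knockdown, is the pseudokinase that breaches the plasma membrane in necroptosis. The first experiment had 4 single libraries: parental cells under DMSO and after 4 h of TBZ, and cells with an shRNA against MLKL (shMLKL) under DMSO and after 12 h of TBZ. The second had 8 libraries, 2 in each of 4 groups: cells with a control shRNA against GFP (shGFP) and shMLKL cells, each under DMSO and after 5 h of TBZ. No label states that libraries 1 and 2 of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The deposited values are FPKM without read counts, so the depth of each library is unknown. From the smallest values, the depth of the second experiment's libraries was estimated at 82.9 to 100.0% of that of shGFP DMSO library 1. Between 9606 and 10047 genes reached 1 FPKM in each of these 8 libraries. Pairs of libraries of a group correlated at 0.989 to 0.992 across genes (Pearson, log2 scale), and libraries of different groups at 0.928 to 0.967. Levels are given as the mean FPKM ± SD with n = 2 libraries, and changes as differences of log2(FPKM + 1), a scale that understates fold changes of genes near 0.

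MLKL (hg19 chromosome 16, 74705753 to 74734789, reverse strand) was lower in the shMLKL line in both experiments. In the second experiment it stood at 3.95 and 3.89 FPKM in the shGFP DMSO libraries, 1.98 and 2.03 in shGFP TBZ, 0.606 and 0.545 in shMLKL DMSO and 0.651 and 0.395 in shMLKL TBZ. The knockdown lowered it under DMSO (log2 difference −1.64, SE 0.10, limma BH-adjusted p = 9.87e-06) and under TBZ (−0.99, SE 0.10, adjusted p = 0.000152). TBZ itself lowered MLKL in shGFP cells (log2 change −0.71, SE 0.10, limma BH-adjusted p = 0.000595). In shMLKL cells its values under TBZ and DMSO differed by −0.05 on the log2 scale (limma BH-adjusted p = 0.698). The TBZ effects of the lines differed (log2 difference 0.66, limma BH-adjusted p = 0.0147), a call that was lost with a pseudocount of 0.1 (0.79, adjusted p = 0.0905) and without shGFP DMSO replicate 1 (0.65, adjusted p = 0.0503). In the first experiment MLKL stood at 6.31 FPKM in parental cells under DMSO (deposited interval 5.65 to 6.97), 6.16 (5.57 to 6.74) after 4 h of TBZ, 0.854 (0.611 to 1.10) in shMLKL cells under DMSO and 2.15 (1.82 to 2.47) after 12 h of TBZ.

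**Figure D1:**
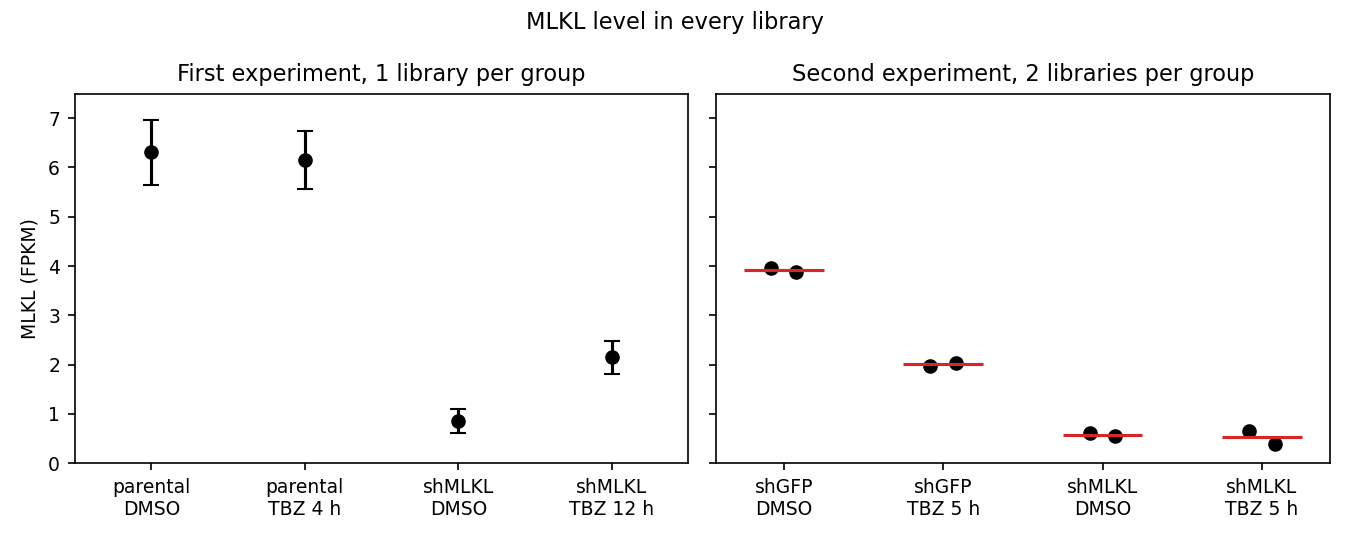
MLKL level in FPKM (vertical axis) in each library of the first experiment (single libraries, bars showing the deposited interval) and of the second (points, 2 libraries per group, with the mean as a line). The shMLKL libraries of the second experiment lie between 0.395 and 0.651 FPKM, all below the shGFP libraries.

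What TBZ changes in cells with their MLKL is answered by TBZ against DMSO in shGFP cells. After 5 h these cells had raised inflammatory transcripts by the largest amounts. CXCL8, the neutrophil chemoattractant interleukin 8 (chromosome 4, 74606223 to 74609433), rose from 16.4 ± 1.22 to 3358 ± 78.0 FPKM (log2 change 7.59, SE 0.20, limma BH-adjusted p = 1.13e-07). ICAM1, a leukocyte adhesion receptor (chromosome 19, 10381517 to 10397291), rose from 2.24 ± 0.156 to 195 ± 0.368 FPKM (log2 change 5.92, SE 0.09, limma BH-adjusted p = 1.23e-08). CCL20, a chemokine for CCR6-bearing lymphocytes and dendritic cells (chromosome 2, 228678558 to 228682280), rose from 6.28 ± 1.66 to 351 ± 9.70 FPKM (log2 change 5.61). CSF2, which encodes GM-CSF (chromosome 5, 131409485 to 131411863), rose from 0.250 ± 0.0567 to 59.0 ± 0.852 FPKM (log2 change 5.59), and GEM, a small GTPase (chromosome 8, 95261485 to 95274547), from 1.16 ± 0.199 to 63.2 ± 2.96 FPKM (log2 change 4.90). The largest falls among genes with values above 0 in all 8 libraries were those of the growth factor BMP4 (chromosome 14, 54416455 to 54423554; from 69.7 ± 3.17 to 7.13 ± 0.444 FPKM, log2 change −3.12), SLITRK6 (from 10.3 ± 0.833 to 0.461 ± 0.0703 FPKM), the focal adhesion protein TNS4 (from 32.9 ± 0.429 to 4.80 ± 0.403 FPKM), the transcription factor GATA2 (from 10.1 ± 0.187 to 1.11 ± 0.0406 FPKM) and C9orf152 (from 6.66 ± 0.187 to 0.523 ± 0.0311 FPKM). At a BH-adjusted p under 0.05, 5844 of 10364 genes were called (limma), 1980 higher and 3864 lower. 537 of them changed at least 2-fold, 381 upward and 156 downward. The median of all genes shifted by −0.121 on the log2 scale, and the called genes that were higher made up 33.9% as deposited, 44.5% with library medians set equal and 40.0% after quantile normalization.

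NF-kB target genes rose together in shGFP cells. Of the NF-kB feedback and survival targets, 28 of 30 measured members rose and 1 fell (28 and 1 adjusted over the list alone; camera BH-adjusted p = 1.38e-25). Among them were TNFAIP3, the deubiquitinase that restrains NF-kB (from 0.815 ± 0.274 to 48.7 ± 0.171 FPKM, log2 change 4.78), and BIRC3, the inhibitor of apoptosis protein cIAP2 (from 5.31 ± 0.398 to 134 ± 0.204 FPKM, log2 change 4.42). Chemokine genes followed: 11 of 13 measured members rose and 1 fell (11 and 1 adjusted over the list alone; camera BH-adjusted p = 7.72e-09). CXCL1, another neutrophil chemoattractant, rose from 6.30 ± 0.0138 to 207 ± 3.30 FPKM (log2 change 4.83). In the list of cytokines and growth factors of inflammation, 15 of 16 measured members rose and 0 fell (15 and 0 adjusted over the list alone; camera BH-adjusted p = 2.08e-12), with the EGF receptor ligand HBEGF rising from 6.25 ± 0.0793 to 54.3 ± 2.84 FPKM. Interferon-stimulated genes went both ways: 19 of 37 measured members rose and 6 fell (19 and 7 adjusted over the list alone; camera BH-adjusted p = 2.50e-05, adjusted p = 0.297 with an estimated correlation). GBP1 rose from 1.62 ± 0.209 to 40.4 ± 1.15 FPKM, GBP2, also an interferon-inducible GTPase, from 4.93 ± 0.584 to 15.5 ± 0.816 FPKM, and the exonuclease gene ISG20 from 2.57 ± 0.299 to 10.3 ± 0.148 FPKM.

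Immediate early and stress genes rose as well. In the list of AP-1 and immediate early genes, 26 of 27 measured members rose and 1 fell (26 and 1 adjusted over the list alone; camera BH-adjusted p = 4.40e-23). The transcription factors EGR1 (chromosome 5, 137801181 to 137805004) and JUN (chromosome 1, 59246463 to 59249785) rose from 6.84 ± 0.913 to 159 ± 1.95 FPKM and from 11.8 ± 1.06 to 158 ± 5.36 FPKM (log2 changes 4.35 and 3.64), and the stress-induced factor ATF3 rose from 15.3 ± 0.497 to 197 ± 6.53 FPKM (log2 change 3.6). MAP kinase feedback regulators also rose: 12 of 15 measured members rose and 2 fell (13 and 2 adjusted over the list alone; camera BH-adjusted p = 1.41e-08, adjusted p = 0.0577 with an estimated correlation). The MAP kinase phosphatases DUSP1 and DUSP5 rose from 3.14 ± 0.407 to 61.3 ± 2.44 FPKM and from 5.03 ± 0.555 to 33.3 ± 2.31 FPKM, and the survival gene IER3 from 13.1 ± 0.0949 to 69.4 ± 2.0 FPKM. In the unfolded protein and integrated stress response, 20 of 30 measured members rose and 1 fell (20 and 1 adjusted over the list alone; camera BH-adjusted p = 8.69e-10). PPP1R15A, the GADD34 phosphatase subunit that reverses eIF2α phosphorylation, rose from 74.6 ± 4.10 to 439 ± 9.18 FPKM, and ERN1, the endoplasmic reticulum sensor IRE1α, from 5.27 ± 0.374 to 14.7 ± 0.939 FPKM. Of the heat shock and oxidative stress genes, 15 of 20 measured members rose and 2 fell (15 and 2 adjusted over the list alone; camera BH-adjusted p = 7.52e-09, adjusted p = 0.0761 with an estimated correlation). Examples were GCLC, of glutathione synthesis (from 37.9 ± 2.82 to 126 ± 1.06 FPKM), and the redox enzymes TXNRD1 (from 145 ± 10.9 to 473 ± 9.90 FPKM) and SRXN1 (from 23.4 ± 1.87 to 72.5 ± 4.02 FPKM).

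Regulators of cell death, p53 targets and sterol genes made up a further set of rises. For regulators of the BCL2 and caspase families, 15 of 25 measured members rose and 4 fell (15 and 4 adjusted over the list alone; camera BH-adjusted p = 2.84e-06). The BH3-only genes PMAIP1 and BBC3 rose from 11.3 ± 0.554 to 62.4 ± 1.15 FPKM and from 5.72 ± 0.328 to 33.4 ± 1.16 FPKM, and the anti-apoptotic MCL1 rose from 75.5 ± 2.81 to 299 ± 4.34 FPKM. Of the p53 targets, 13 of 21 measured members rose and 4 fell (13 and 4 adjusted over the list alone; camera BH-adjusted p = 1.26e-06, adjusted p = 0.0577 with an estimated correlation). CDKN1A, the cell cycle inhibitor p21, rose from 13.6 ± 1.34 to 88.7 ± 0.476 FPKM, and the antiproliferative BTG2 from 3.41 ± 0.132 to 40.0 ± 1.68 FPKM. Among genes of cholesterol synthesis and uptake, 14 of 23 measured members rose and 1 fell (14 and 1 adjusted over the list alone; camera BH-adjusted p = 2.43e-09, adjusted p = 0.0506 with an estimated correlation). INSIG1, a sterol-sensing brake on this pathway, rose from 6.18 ± 0.611 to 96.1 ± 2.46 FPKM (log2 change 3.76) and the synthase HMGCS1 from 17.9 ± 0.127 to 131 ± 6.25 FPKM.

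Cell cycle, WNT and corepressor genes fell in shGFP cells. In the cell cycle list, 1 of 36 measured members rose and 29 fell (1 and 31 adjusted over the list alone; camera BH-adjusted p = 1.58e-07). The mitotic kinase gene PLK1 fell from 28.7 ± 0.361 to 13.6 ± 0.186 FPKM and the mitotic kinesin KIF20A from 8.82 ± 0.486 to 3.94 ± 0.0445 FPKM. For WNT targets and stem cell genes, 0 of 10 measured members rose and 7 fell (0 and 7 adjusted over the list alone; camera BH-adjusted p = 0.00290, adjusted p = 0.0613 with an estimated correlation). RNF43 and AXIN2, negative feedback genes of WNT signalling, fell from 19.6 ± 0.160 to 5.02 ± 0.0424 FPKM and from 4.29 ± 0.386 to 0.593 ± 0.0233 FPKM, and MYC fell from 55.7 ± 0.584 to 30.9 ± 0.192 FPKM. In the TRIM28 corepressor list, 0 of 16 measured members rose and 12 fell (0 and 12 adjusted over the list alone; camera BH-adjusted p = 0.0113, adjusted p = 0.0761 with an estimated correlation), with UHRF1, a maintenance factor of DNA methylation (from 4.59 ± 0.0408 to 1.49 ± 0.206 FPKM), the heterochromatin protein gene CBX3 (from 126 ± 0.999 to 88.8 ± 2.86 FPKM) and the histone methyltransferase SETDB1 (from 12.1 ± 0.741 to 8.48 ± 0.234 FPKM) among the falls. The necroptosis machinery did not pass the list test: 11 of 33 measured members rose and 9 fell (11 and 11 adjusted over the list alone; camera BH-adjusted p = 0.0568). The deubiquitinase CYLD rose from 1.5 ± 0.104 to 6.17 ± 0.271 FPKM and CFLAR, the caspase 8 regulator cFLIP, from 37.1 ± 3.58 to 81.7 ± 4.52 FPKM. BIRC2, which encodes cIAP1, rose from 21.7 ± 0.0405 to 36.5 ± 1.48 FPKM and the kinase gene RIPK1 from 9.28 ± 0.353 to 12.0 ± 0.608 FPKM (limma BH-adjusted p = 0.00142). The MLKL-activating kinase RIPK3 fell from 2.71 ± 0.539 to 1.82 ± 0.111 FPKM (limma BH-adjusted p = 0.0187). The call was lost after quantile normalization (−0.24, adjusted p = 0.106) and without shGFP DMSO replicate 1 or TBZ replicate 2. CASP8 stood at 15.5 ± 1.09 FPKM under DMSO and 15.0 ± 0.110 under TBZ (limma BH-adjusted p = 0.600), and TNFRSF1A, the receptor TNFR1, at 19.6 ± 1.23 and 17.8 ± 1.86 (adjusted p = 0.152).

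**Figure D2:**
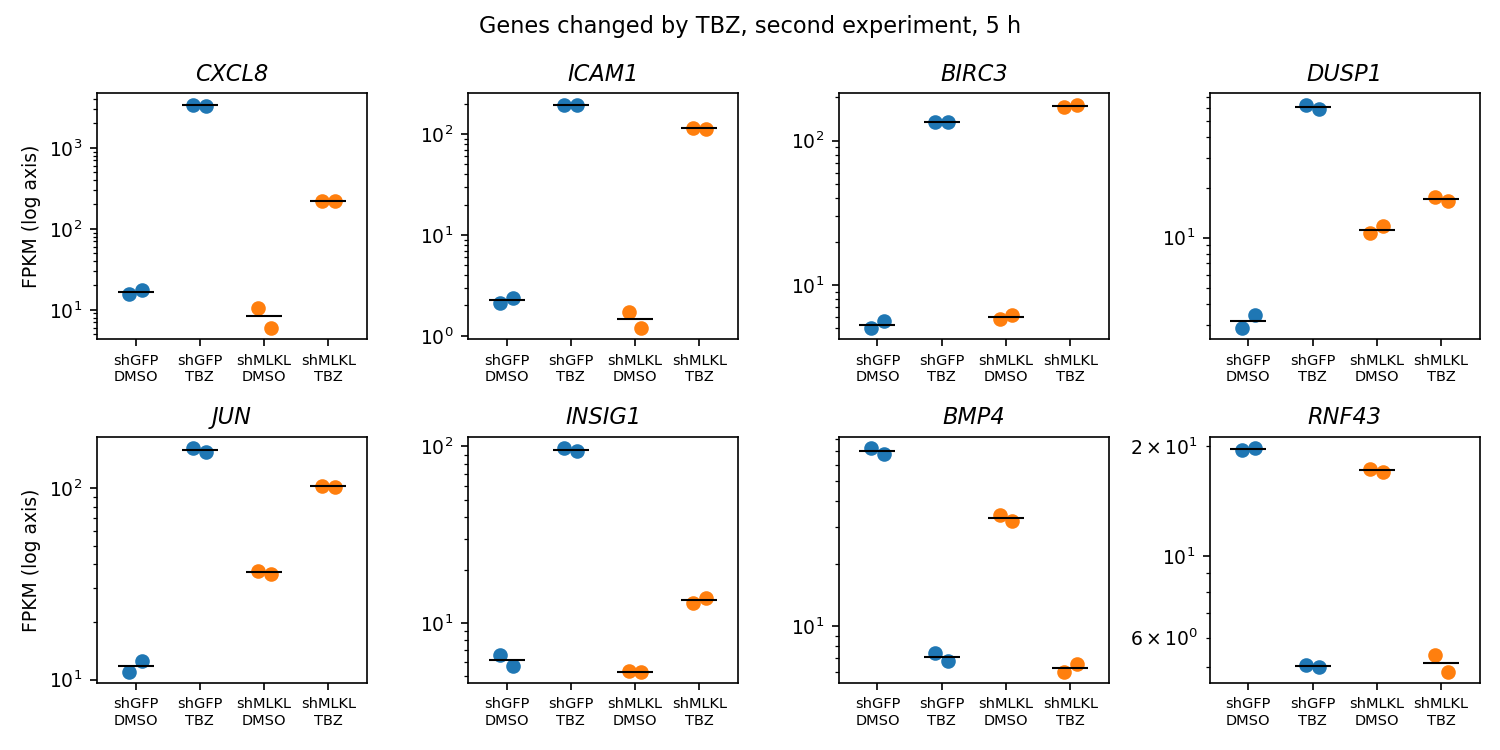
FPKM (vertical log axis) of 8 named genes in each library of the second experiment (points, 2 libraries per group, with the mean as a line). CXCL8 stood at 3358 FPKM in shGFP and 218 in shMLKL cells under TBZ.

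**Figure D3:**
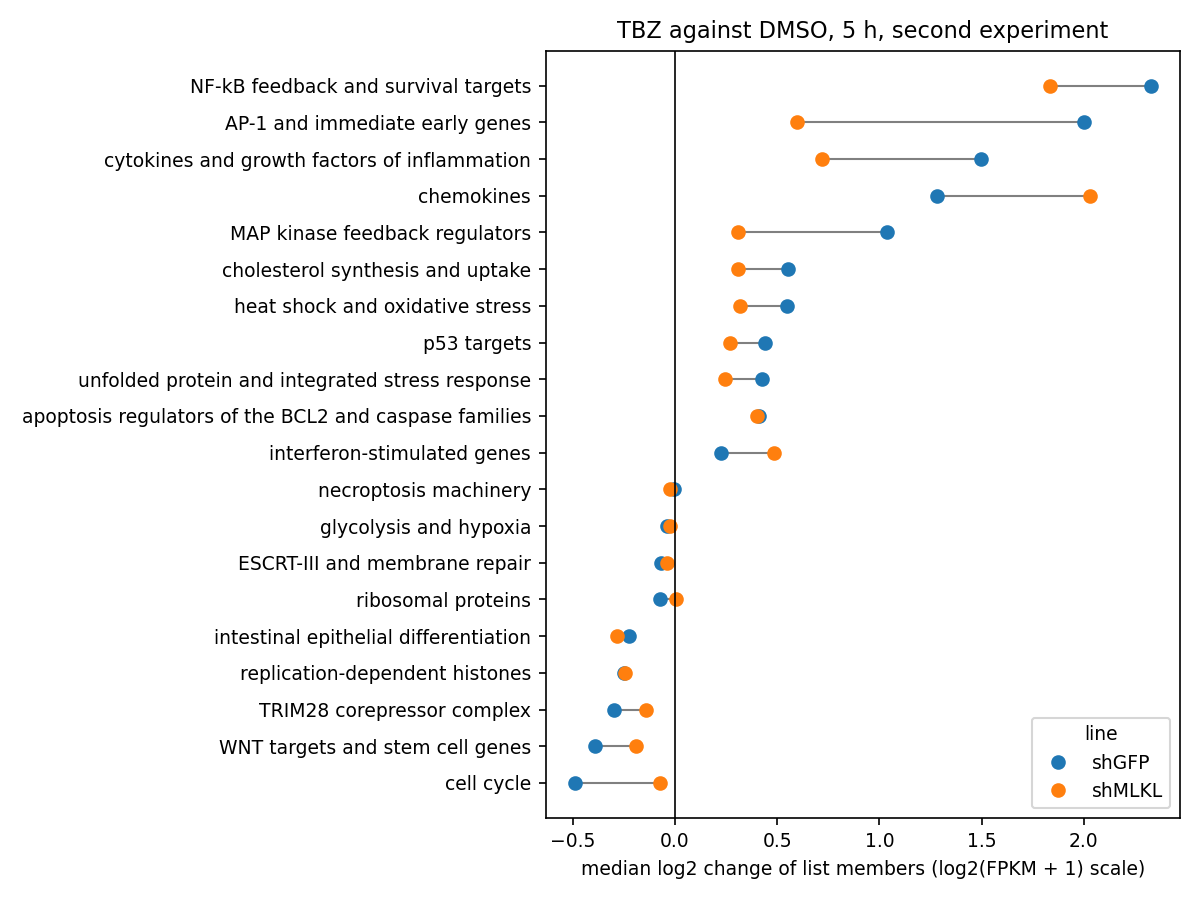
Median log2 change of the members of each gene list with TBZ after 5 h, in shGFP and shMLKL cells (horizontal axis, scale of log2(FPKM + 1)). The AP-1 and immediate early list stood at 2.00 in shGFP and 0.60 in shMLKL cells.

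The same question was put to cells depleted of MLKL by TBZ against DMSO in the shMLKL line. NF-kB target genes rose here too. ICAM1 rose from 1.45 ± 0.366 to 114 ± 2.06 FPKM (log2 change 5.55, SE 0.09, limma BH-adjusted p = 3.17e-08), BIRC3 from 6.0 ± 0.293 to 174 ± 4.65 FPKM (log2 change 4.65), CXCL8 from 8.28 ± 3.31 to 218 ± 0.326 FPKM (log2 change 4.61), TNFAIP3 from 0.634 ± 0.139 to 30.5 ± 0.644 FPKM (log2 change 4.27) and NFKBIA, the inhibitor IkBα, from 9.48 ± 0.566 to 163 ± 2.44 FPKM (log2 change 3.97). The largest falls among genes with values above 0 in all 8 libraries were those of the WNT antagonist DKK1 (chromosome 10, 54074041 to 54077417; from 26.4 ± 0.869 to 1.46 ± 0.0769 FPKM, log2 change −3.48, SE 0.07, limma BH-adjusted p = 6.08e-08), the growth factor FGF19 (from 13.7 ± 0.725 to 1.81 ± 0.00223 FPKM), SLITRK6 (from 5.52 ± 0.413 to 0.352 ± 0.0669 FPKM), TNS4 (from 14.2 ± 1.44 to 2.19 ± 0.169 FPKM) and BMP4 (from 33.2 ± 1.41 to 6.32 ± 0.382 FPKM). Of 10364 genes, 3891 were called (limma, BH), 2070 higher and 1821 lower. 218 rose and 78 fell at least 2-fold. The median of all genes shifted by −0.004, and the called genes that were higher made up 53.2% as deposited, 45.8% with library medians set equal and 47.0% after quantile normalization.

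Inflammatory and interferon genes led the list results in shMLKL cells. Of the NF-kB feedback and survival targets, 28 of 30 measured members rose and 1 fell (29 and 1 adjusted over the list alone; camera BH-adjusted p = 1.15e-22). Among chemokines, 11 of 13 measured members rose and 0 fell (12 and 1 adjusted over the list alone; camera BH-adjusted p = 1.75e-09, adjusted p = 0.0792 with an estimated correlation), with CCL20 rising from 2.91 ± 0.862 to 47.9 ± 2.57 FPKM and CXCL1 from 3.40 ± 0.468 to 26.6 ± 0.410 FPKM. For cytokines and growth factors of inflammation, 11 of 16 measured members rose and 1 fell (12 and 1 adjusted over the list alone; camera BH-adjusted p = 4.11e-05, adjusted p = 0.0792 with an estimated correlation). The cytokine IL32 rose from 3.07 ± 0.263 to 37.6 ± 2.38 FPKM, CSF2 from 0.316 ± 0.160 to 7.96 ± 1.21 FPKM and IL23A, a subunit of interleukin 23, from 0.216 ± 0.00864 to 4.76 ± 1.13 FPKM. Of the interferon-stimulated genes, 28 of 37 measured members rose and 0 fell (30 and 0 adjusted over the list alone; camera BH-adjusted p = 4.58e-12, adjusted p = 0.135 with an estimated correlation). GBP1 rose from 0.449 ± 0.0195 to 7.33 ± 0.261 FPKM, the RNA sensor IFIH1 from 18.8 ± 0.0630 to 66.4 ± 0.286 FPKM and the pro-apoptotic XAF1 from 1.89 ± 0.125 to 7.15 ± 0.185 FPKM. In the AP-1 and immediate early list, 21 of 27 measured members rose and 2 fell (22 and 2 adjusted over the list alone; camera BH-adjusted p = 4.53e-09, adjusted p = 0.135 with an estimated correlation). EGR1 rose from 4.32 ± 0.495 to 28.3 ± 1.04 FPKM, BTG2 from 1.66 ± 0.304 to 9.70 ± 0.269 FPKM and the AP-1 subunit FOSL1 from 33.6 ± 0.250 to 118 ± 7.26 FPKM. MAP kinase feedback regulators did not pass the list test: 8 of 15 measured members rose and 3 fell (8 and 4 adjusted over the list alone; camera BH-adjusted p = 0.224). DUSP10 rose from 1.24 ± 0.0477 to 4.18 ± 0.254 FPKM, whereas DUSP4 fell from 10.7 ± 0.915 to 3.40 ± 0.137 FPKM and the EGF receptor inhibitor ERRFI1 from 238 ± 0.122 to 91.6 ± 2.91 FPKM.

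Death regulators, stress genes and sterol genes also rose in shMLKL cells. For the BCL2 and caspase families, 14 of 25 measured members rose and 4 fell (15 and 4 adjusted over the list alone; camera BH-adjusted p = 0.000493, adjusted p = 0.0792 with an estimated correlation). The death ligand TRAIL (TNFSF10) rose from 4.65 ± 0.417 to 34.5 ± 0.494 FPKM, its receptor gene TNFRSF10B from 31.6 ± 0.0683 to 86.1 ± 1.41 FPKM and BBC3 from 8.12 ± 0.296 to 30.1 ± 1.01 FPKM. In the unfolded protein and integrated stress response, 20 of 30 measured members rose and 1 fell (22 and 1 adjusted over the list alone; camera BH-adjusted p = 6.44e-08, adjusted p = 0.0792 with an estimated correlation). ATF3 rose from 32.1 ± 2.54 to 77.9 ± 3.29 FPKM, ERN1 from 11.7 ± 0.809 to 22.2 ± 0.135 FPKM and PPP1R15A from 212 ± 11.5 to 382 ± 17.2 FPKM. Of the heat shock and oxidative stress genes, 13 of 20 measured members rose and 1 fell (14 and 2 adjusted over the list alone; camera BH-adjusted p = 5.64e-05, adjusted p = 0.192 with an estimated correlation), among them SRXN1 (from 30.4 ± 0.363 to 68.8 ± 0.955 FPKM), the co-chaperone DNAJA1 (from 68.1 ± 1.28 to 149 ± 3.73 FPKM) and OSGIN1 (from 4.52 ± 0.328 to 8.73 ± 1.17 FPKM). Of the p53 targets, 11 of 21 measured members rose and 2 fell (11 and 2 adjusted over the list alone; camera BH-adjusted p = 0.000892, adjusted p = 0.135 with an estimated correlation). Of the cholesterol genes, 13 of 23 measured members rose and 2 fell (15 and 2 adjusted over the list alone; camera BH-adjusted p = 5.64e-05, adjusted p = 0.135 with an estimated correlation), with INSIG1 rising from 5.32 ± 0.00511 to 13.5 ± 0.681 FPKM, the isomerase IDI1 from 18.3 ± 0.227 to 32.4 ± 1.78 FPKM and the sterol carrier STARD4 from 4.66 ± 0.178 to 8.64 ± 0.470 FPKM. WNT targets and stem cell genes fell: 1 of 10 measured members rose and 4 fell (1 and 7 adjusted over the list alone; camera BH-adjusted p = 0.00381, adjusted p = 0.119 with an estimated correlation). RNF43 fell from 17.2 ± 0.195 to 5.12 ± 0.389 FPKM, AXIN2 from 2.10 ± 0.116 to 0.954 ± 0.0937 FPKM and MYC from 41.1 ± 0.479 to 26.6 ± 0.461 FPKM. The cell cycle list did not pass (5 of 36 measured members rose and 9 fell; 5 and 9 adjusted over the list alone; camera BH-adjusted p = 0.0664), although it was called after quantile normalization (camera BH-adjusted p = 0.0293). PLK1 fell from 20.2 ± 0.541 to 12.3 ± 0.579 FPKM and BUB1B, of the spindle checkpoint, from 15.9 ± 0.557 to 10.2 ± 0.552 FPKM. In the TRIM28 corepressor list, 2 of 16 measured members rose and 7 fell (2 and 7 adjusted over the list alone; camera BH-adjusted p = 0.224). UHRF1 fell from 2.15 ± 0.0224 to 1.18 ± 0.436 FPKM, SETDB1 from 11.1 ± 0.969 to 8.51 ± 0.625 FPKM and the helicase CHD3 from 11.6 ± 0.676 to 9.08 ± 0.193 FPKM.

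In the necroptosis machinery of shMLKL cells, 12 of 33 measured members rose and 6 fell (12 and 8 adjusted over the list alone; camera BH-adjusted p = 0.217). CYLD rose from 2.27 ± 0.170 to 8.94 ± 0.0180 FPKM, the adaptor TRAF2 from 4.22 ± 0.888 to 8.75 ± 0.508 FPKM, BIRC2 from 29.3 ± 0.240 to 43.6 ± 0.425 FPKM, CFLAR from 40.3 ± 1.32 to 58.3 ± 2.5 FPKM and RIPK1 from 8.87 ± 0.291 to 11.5 ± 0.00516 FPKM. TNFRSF1A fell from 24.2 ± 0.631 to 20.3 ± 0.295 FPKM (limma BH-adjusted p = 0.0302). RIPK3 stood at 2.61 ± 0.268 FPKM under DMSO and 1.93 ± 0.0590 under TBZ (limma BH-adjusted p = 0.0681), and CASP8 at 19.1 ± 0.177 and 21.4 ± 1.58 (adjusted p = 0.0869). The TNFRSF1A call was lost without any 1 of the 4 shMLKL libraries and the UHRF1 call without either shMLKL DMSO library. The SETDB1 call was lost without shMLKL DMSO library 2 or TBZ library 1.

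Whether the TBZ response depended on the line was tested by the difference of the TBZ effects, shMLKL minus shGFP. The rises of immediate early, growth factor and MAP kinase genes were smaller in shMLKL cells, as were the falls of cell cycle genes. Cell cycle genes already stood lower in shMLKL cells under DMSO (list mean log2 difference −0.439) and lay at −0.028 under TBZ. For them the difference of effects cannot tell a smaller response from a lower starting level. GEM, which rose 4.90 on the log2 scale in shGFP and 1.46 in shMLKL cells, had the largest negative difference among genes with values above 0 (log2 difference −3.43, SE 0.16, limma BH-adjusted p = 1.79e-05). DUSP1 (chromosome 5, 172195093 to 172198203; −3.34, SE 0.11, adjusted p = 4.78e-06, limma) and RHOB, a small GTPase of the actin skeleton (chromosome 2, 20646835 to 20649201; −3.20, SE 0.09, adjusted p = 2.70e-06), followed. NR4A1, an immediate early nuclear receptor, rose from 1.02 ± 0.334 to 15.2 ± 1.05 FPKM in shGFP and stood at 1.43 ± 0.130 and 1.15 ± 0.00145 in shMLKL cells (log2 difference −3.18). AKAP12, a kinase scaffold, rose from 1.27 ± 0.278 to 5.22 ± 0.251 FPKM in shGFP and fell from 9.47 ± 1.95 to 2.29 ± 0.195 FPKM in shMLKL cells (log2 difference −3.12). Positive differences were led by HOXA13, a homeobox gene of the hindgut (from 10.5 ± 0.322 to 1.34 ± 0.243 FPKM in shGFP, 3.72 ± 0.0194 and 2.89 ± 0.0464 in shMLKL; log2 difference 2.02), GATA2 (1.65), the BMP and WNT antagonist SOSTDC1 (1.55), HIST1H2BL (1.41) and the interferon-induced chemokine CXCL10 (1.38). CXCL10 rose from 10.9 ± 0.589 to 17.6 ± 0.118 FPKM in shGFP and from 2.03 ± 0.250 to 11.3 ± 0.886 FPKM in shMLKL cells. Limma called 2306 of 10364 genes, 1512 with a positive and 794 with a negative difference. 195 differed at least 2-fold, 51 positive and 144 negative. The median of all genes lay at 0.103, and positive differences made up 65.6% of the calls as deposited, 38.9% with library medians set equal and 50.8% after quantile normalization. The count fell whichever library was left out, and HIST1H2BL lost its call without each of 5.

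Immediate early and MAP kinase genes differed most as lists by the mean log2 difference. In the AP-1 and immediate early list, 1 of 27 measured members had a positive difference and 24 a negative one (1 and 26 adjusted over the list alone; camera BH-adjusted p = 4.80e-32). EGR1, JUN and ATF3 differed by −1.89, −2.17 and −2.35 on the log2 scale. For MAP kinase feedback regulators, 0 of 15 measured members were positive and 12 negative (0 and 13 adjusted over the list alone; camera BH-adjusted p = 1.08e-15). ERRFI1 rose from 219.9 ± 18.0 to 361 ± 7.17 FPKM in shGFP and fell from 238 ± 0.122 to 91.6 ± 2.91 FPKM in shMLKL cells. Among cytokines and growth factors, 0 of 16 measured members were positive and 10 negative (0 and 10 adjusted over the list alone; camera BH-adjusted p = 8.54e-10). CSF2 and HBEGF differed by −2.82 and −2.73. NF-kB feedback and survival targets gave a smaller shift: 3 of 30 measured members were positive and 15 negative (4 and 18 adjusted over the list alone; camera BH-adjusted p = 8.54e-10). Within that list ICAM1 differed by −0.36 (limma BH-adjusted p = 0.0789) and BIRC3 by 0.23 (adjusted p = 0.0654), while TNFAIP3 (−0.52, adjusted p = 0.0435) and NFKBIA (−0.20, adjusted p = 0.0480) were called but lost the call with a pseudocount of 0.5 (adjusted p = 0.131 and 0.0793, limma). ICAM1 gained it with library medians set equal (adjusted p = 0.0407, limma). For chemokines, 3 of 13 measured members were positive and 6 negative (5 and 7 adjusted over the list alone; camera BH-adjusted p = 0.00772, adjusted p = 0.154 with an estimated correlation), and with library medians set equal the list was not called (camera BH-adjusted p = 0.0537). CXCL8 and CXCL1 differed by −2.98 and −2.18. Cholesterol genes gave 0 of 23 measured members positive and 11 negative (0 and 11 adjusted over the list alone; camera BH-adjusted p = 3.83e-09, adjusted p = 0.0713 with an estimated correlation), with INSIG1 and HMGCS1 at −2.57 and −2.10.

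Stress, p53 and death regulators had smaller negative shifts. In the unfolded protein and integrated stress response, 4 of 30 measured members were positive and 13 negative (6 and 14 adjusted over the list alone; camera BH-adjusted p = 1.84e-05, adjusted p = 0.0773 with an estimated correlation), and PPP1R15A differed by −1.69. Heat shock and oxidative stress genes gave 0 of 20 measured members positive and 9 negative (0 and 11 adjusted over the list alone; camera BH-adjusted p = 7.84e-07, adjusted p = 0.129 with an estimated correlation), among them TXNRD1 (−0.89). Of the p53 targets, 2 of 21 measured members were positive and 9 negative (4 and 10 adjusted over the list alone; camera BH-adjusted p = 1.58e-05, adjusted p = 0.0773 with an estimated correlation). CDKN1A differed by −1.57. For the BCL2 and caspase families, 3 of 25 measured members were positive and 6 negative (3 and 7 adjusted over the list alone; camera BH-adjusted p = 0.00560, adjusted p = 0.0773 with an estimated correlation), with MCL1 at −1.39 and TNFSF10 at 1.10. Cell cycle genes went the other way: 26 of 36 measured members were positive and 0 negative (28 and 0 adjusted over the list alone; camera BH-adjusted p = 3.83e-09), with KIF20A at 0.98. The TRIM28 corepressor list gave 7 of 16 measured members positive and 0 negative (9 and 0 adjusted over the list alone; camera BH-adjusted p = 0.00641, adjusted p = 0.0773 with an estimated correlation), with CBX3 at 0.32. WNT targets and stem cell genes were not called (4 of 10 measured members positive and 0 negative, 4 and 0 adjusted over the list alone; camera BH-adjusted p = 0.0599), but were after quantile normalization (camera BH-adjusted p = 0.0327). AXIN2 differed by 1.06. Interferon-stimulated genes shifted upward: 19 of 37 measured members were positive and 4 negative (20 and 4 adjusted over the list alone; camera BH-adjusted p = 0.00462, adjusted p = 0.413 with an estimated correlation). XAF1 differed by 1.08 and GBP1 by −1.46. In the necroptosis machinery, 4 of 33 measured members were positive and 4 negative (4 and 4 adjusted over the list alone; camera BH-adjusted p = 0.367). CFLAR differed by −0.60, and RIPK1, RIPK3, CASP8 and BIRC2 by −0.00, 0.09, 0.20 and −0.17 (limma BH-adjusted p = 0.994, 0.704, 0.147 and 0.0636). BIRC2 was called with library medians set equal (limma, −0.26, adjusted p = 0.0233).

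Across genes, which are not independent replicates, the TBZ effects of the lines correlated with a Spearman rho of 0.722 and a Pearson r of 0.758 over the 6756 genes called in either line, of which 80.7% changed in the same direction. Over all 10364 genes rho was 0.655 and r 0.698. Of the genes called higher, 1366 were shared by both lines, against 395 for independent lists of these sizes. Of those called lower, 1443 were shared, against 679, and 170 genes were called in opposite directions.

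Cells of the shMLKL and shGFP lines were compared under DMSO to show how the lines differed before TBZ. By camera at the preset correlation, interferon-stimulated and cell cycle genes were lower and unfolded protein response genes higher in shMLKL cells, calls that were lost with an estimated correlation (camera BH-adjusted p = 0.397, 0.186 and 0.186). The largest single difference among genes with values above 0 was that of GABRP, a GABA receptor subunit (chromosome 5, 170210723 to 170241050), which stood at 10.1 ± 0.188 FPKM in shGFP and 0.809 ± 0.211 in shMLKL (log2 difference −2.62, SE 0.10, limma BH-adjusted p = 1.88e-06). The chloride channel gene CFTR (chromosome 7, 117120017 to 117308718) stood at 9.45 ± 0.690 and 0.885 ± 0.0641 (−2.47), the interferon-induced IFI44L at 10.1 ± 0.552 and 1.20 ± 0.0121 (−2.34), PPP1R1B at 6.31 ± 0.460 and 0.552 ± 0.0299 (−2.23) and the aldehyde dehydrogenase ALDH3A1 at 5.56 ± 0.148 and 0.490 ± 0.413 (−2.17). Higher in shMLKL cells were C3orf52 (chromosome 3, 111805182 to 111837073; 2.98 ± 0.299 and 19.8 ± 2.39, 2.38), AKAP12 (1.27 ± 0.278 and 9.47 ± 1.95), SCEL, of the cornified envelope (19.6 ± 2.03 and 86.8 ± 6.73), the adhesion molecule ALCAM (1.68 ± 0.332 and 9.91 ± 0.640) and the chaperone HSPA13 (6.23 ± 1.04 and 28.4 ± 0.205). Of 10364 genes, 6539 were called (limma, BH), 1899 higher and 4640 lower in shMLKL. 162 were at least 2-fold higher and 252 at least 2-fold lower. The median of all genes lay at −0.162, and the called genes that were higher made up 29% as deposited, 53.1% with library medians set equal and 47.5% after quantile normalization.

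Interferon-stimulated, cell cycle, WNT and TRIM28 corepressor genes were lower in shMLKL cells under DMSO. Of the interferon-stimulated genes, 2 of 37 measured members were higher and 29 lower (2 and 29 adjusted over the list alone; camera BH-adjusted p = 0.000556, adjusted p = 0.397 with an estimated correlation). Of the cell cycle genes, 1 of 36 measured members was higher and 29 lower (1 and 29 adjusted over the list alone; camera BH-adjusted p = 0.000437, adjusted p = 0.186 with an estimated correlation). For WNT targets and stem cell genes, 0 of 10 measured members were higher and 8 lower (0 and 8 adjusted over the list alone; camera BH-adjusted p = 0.0109, adjusted p = 0.226 with an estimated correlation), and for the TRIM28 corepressor list, 0 of 16 measured members were higher and 15 lower (0 and 15 adjusted over the list alone; camera BH-adjusted p = 0.00202, adjusted p = 0.186 with an estimated correlation). Stress and immediate early genes were higher. In the unfolded protein and integrated stress response, 19 of 30 measured members were higher and 5 lower (19 and 6 adjusted over the list alone; camera BH-adjusted p = 2.75e-07, adjusted p = 0.186 with an estimated correlation). In the AP-1 and immediate early list, 15 of 27 measured members were higher and 5 lower (15 and 5 adjusted over the list alone; camera BH-adjusted p = 0.000113, adjusted p = 0.381 with an estimated correlation). Among MAP kinase feedback regulators, 8 of 15 measured members were higher and 3 lower (8 and 3 adjusted over the list alone; camera BH-adjusted p = 0.000437, adjusted p = 0.254 with an estimated correlation). PPP1R15A stood at 74.6 ± 4.10 FPKM in shGFP and 212 ± 11.5 in shMLKL cells, JUN at 11.8 ± 1.06 and 36.3 ± 0.898 and DUSP5 at 5.03 ± 0.555 and 18.8 ± 0.753. Cytokines and growth factors gave 6 of 16 measured members higher and 2 lower (6 and 2 adjusted over the list alone; camera BH-adjusted p = 0.0109, adjusted p = 0.243 with an estimated correlation), heat shock and oxidative stress genes 11 of 20 measured members higher and 6 lower (11 and 6 adjusted over the list alone; camera BH-adjusted p = 0.00579, adjusted p = 0.381 with an estimated correlation) and p53 targets 9 of 21 measured members higher and 7 lower (9 and 7 adjusted over the list alone; camera BH-adjusted p = 0.0388, adjusted p = 0.381 with an estimated correlation). Replication-dependent histones, a sign of poly-A selection, gave 7 of 17 measured members higher and 3 lower (7 and 3 adjusted over the list alone; camera BH-adjusted p = 0.0219, adjusted p = 0.442 with an estimated correlation). The heat shock call was lost after quantile normalization (camera BH-adjusted p = 0.0791) and the p53 call with library medians set equal (camera BH-adjusted p = 0.063). The lists of NF-kB targets, chemokines, necroptosis, the BCL2 and caspase families and cholesterol genes were not called (camera BH-adjusted p = 0.0900, 0.565, 0.376, 0.244 and 0.0674). Of the necroptosis genes, TNFRSF1A, CASP8, BIRC2 and BIRC3 differed by 0.30, 0.28, 0.42 and 0.15 (limma BH-adjusted p = 0.00848, 0.00553, 7.85e-05 and 0.0390), and RIPK1, RIPK3 and CFLAR by −0.06, −0.03 and 0.12 (adjusted p = 0.371, 0.799 and 0.183, limma). The BIRC3 call was lost in 9 alternatives (limma BH-adjusted p = 0.0529 to 0.206).

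Under TBZ the same lines were compared to show where they stood after 5 h. By camera at the preset correlation, chemokine and immediate early genes were lower in shMLKL cells, calls that were lost with an estimated correlation (camera BH-adjusted p = 0.281 for both). CXCL8 stood at 3358 ± 78.0 FPKM in shGFP and 218 ± 0.326 in shMLKL (log2 difference −3.94, SE 0.20, limma BH-adjusted p = 8.40e-06). The matrix glycoprotein THBS1 (chromosome 15, 39873280 to 39889668) stood at 30.4 ± 1.28 and 1.59 ± 0.107 (−3.6), the elastase inhibitor PI3 at 29.9 ± 3.18 and 1.93 ± 1.66 (−3.52), CXCL1 at 207 ± 3.30 and 26.6 ± 0.410 (−2.91) and NR4A1 at 15.2 ± 1.05 and 1.15 ± 0.00145 (−2.91). Higher were SCEL (7.14 ± 0.0206 and 42.4 ± 1.60, 2.41), the trypsinogen PRSS1 (2.48 ± 0.325 and 14.9 ± 1.36, 2.19), the trypsin inhibitor SPINK1 (2.31 ± 0.625 and 11.2 ± 0.0197, 1.89), the metallothionein MT2A (18.6 ± 2.23 and 69.9 ± 4.49, 1.86) and GABARAPL1, of the autophagosome (6.56 ± 0.0816 and 26.0 ± 0.773, 1.84). Limma called 5360 of 10364 genes at the BH threshold, 2144 higher and 3216 lower, 94 and 182 of them by at least 2-fold. The median of all genes lay at −0.056, and higher genes made up 40.0% of the calls as deposited, 54.6% with library medians set equal and 52.1% after quantile normalization.

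Immediate early, sterol and inflammatory lists were lower in shMLKL cells under TBZ. In the AP-1 and immediate early list, 0 of 27 measured members were higher and 26 lower (0 and 26 adjusted over the list alone; camera BH-adjusted p = 5.37e-12, adjusted p = 0.281 with an estimated correlation). Among cholesterol genes, 0 of 23 measured members were higher and 20 lower (0 and 22 adjusted over the list alone; camera BH-adjusted p = 7.72e-09, adjusted p = 0.281 with an estimated correlation). Among MAP kinase feedback regulators, 2 of 15 measured members were higher and 11 lower (2 and 11 adjusted over the list alone; camera BH-adjusted p = 0.00653, adjusted p = 0.281 with an estimated correlation). NF-kB targets gave 5 of 30 measured members higher and 17 lower (5 and 17 adjusted over the list alone; camera BH-adjusted p = 0.0356, adjusted p = 0.281 with an estimated correlation), chemokines 1 of 13 measured members higher and 8 lower (1 and 9 adjusted over the list alone; camera BH-adjusted p = 0.0356, adjusted p = 0.281 with an estimated correlation) and cytokines and growth factors 3 of 16 measured members higher and 9 lower (3 and 9 adjusted over the list alone; camera BH-adjusted p = 0.0356, adjusted p = 0.281 with an estimated correlation). Without genes listed at 0 the cytokine call was lost (camera BH-adjusted p = 0.107). HMGCS1 stood at 131 ± 6.25 FPKM in shGFP and 31.9 ± 2.36 in shMLKL, HBEGF at 54.3 ± 2.84 and 9.80 ± 0.986 and CCL20 at 351 ± 9.70 and 47.9 ± 2.57. The unfolded protein and integrated stress response was higher: 13 of 30 measured members were higher and 5 lower (13 and 6 adjusted over the list alone; camera BH-adjusted p = 0.0356, adjusted p = 0.281 with an estimated correlation). This call was lost after quantile normalization (camera BH-adjusted p = 0.0741). The other lists were not called, including interferon-stimulated genes (camera BH-adjusted p = 0.149), cell cycle (0.746) and necroptosis (0.641).

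Some genes picked by the size of their change were listed at 0 in at least 1 library, and no fold is given for them here. Their FPKM follow in the order shGFP DMSO 1 and 2, shGFP TBZ 1 and 2, shMLKL DMSO 1 and 2, shMLKL TBZ 1 and 2. MGAT4B was listed at 39.3, 40.2, 0, 0, 40.4, 41.0, 0 and 0. BRI3 had 35.9, 33.2, 0, 0, 0, 0, 0 and 0. TGIF2-C20orf24 was listed at 20.1, 14.8, 0, 0, 0, 0, 0 and 0. BLZF1 had 16.2, 17.1, 0, 0, 18.7, 19.6, 20.8 and 20.5. DUS4L was listed at 14.3, 13.6, 0, 0, 0, 0, 0 and 0. FAM118B had 11.6, 13.7, 14.4, 17.7, 0, 0, 17.7 and 16.4. TMEM243 was listed at 23.6, 25.5, 34.9, 23.5, 20.1, 20.5, 0 and 0. RAD17 had 10.9, 13.6, 0, 0, 11.3, 10.6, 0 and 0. ACOT13 was listed at 9.55, 7.81, 7.06, 7.99, 5.68, 5.91, 0 and 0. GLIPR1 had 0, 0, 13.5, 13.7, 0, 0, 0 and 0. CYB5R3 was listed at 0, 0, 13.1, 0, 10.4, 12.2, 10.4 and 10.6. NIT1 had 0, 0, 6.72, 0, 10.1, 8.35, 0 and 8.02. RPL36A was listed at 52.4, 46.3, 40.2, 56.7, 0, 0, 42.1 and 0. RUVBL1 had 41.4, 39.5, 27.5, 26.9, 0, 0, 0 and 0. RFC4 was listed at 19.8, 19.0, 11.3, 11.8, 0, 0, 0 and 0. LARP6 had 6.08, 7.33, 0, 5.51, 18.1, 12.5, 11.3 and 9.81. IL17C was listed at 0.133, 0.217, 7.34, 8.86, 0, 0, 3.39 and 2.73. CDC25C had 5.90, 6.18, 0, 0, 3.57, 3.55, 0 and 0. Of the 10364 genes tested, 177 were listed at 0 in at least 1 library, and 80 of these reached 5 FPKM in another. Highly expressed genes were among them: EIF2S2, a translation initiation factor chosen after its values were seen, was listed at 0 in shGFP DMSO 2 and shGFP TBZ 1 and between 150.6 and 171 in the other 6 libraries, and HMGB1 at 0 in shMLKL TBZ 1 and between 91.6 and 109 elsewhere.

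The first experiment had single libraries, so no test was run and ratios carry no error. After 4 h of TBZ in parental cells, inflammatory genes stood far above DMSO. CXCL8 went from 1.13 to 1110 FPKM, ICAM1 from 2.53 to 231 and CCL20 from 0.294 to 60.6, the largest ratios among genes not listed at 0. BMP4 went from 153 to 9.81, the pseudogene WASH3P from 27.6 to 1.72 and the adhesion protein AMIGO2 from 40.7 to 3.48. CSF2 stood at 0.274 and 33.0 FPKM under DMSO and TBZ, EGR1 at 28.2 and 274, DUSP1 at 10.2 and 141, CDKN1A at 48.9 and 355, INSIG1 at 4.27 and 128, RNF43 at 42.3 and 3.73 and PLK1 at 20.2 and 4.88. Of 10260 genes, 2388 differed at least 2-fold, 973 higher and 1415 lower, around a median log2 ratio of −0.23. Percentiles are places among 10000 random lists of the same size matched on expression. In the NF-kB list, 22 of 28 measured members were at least 2-fold higher and 2 lower (median log2 ratio 2.02, percentile 100.0). In the AP-1 and immediate early list, 24 of 28 measured members were at least 2-fold higher and 3 lower (median log2 ratio 2.17, percentile 100.0). In the cell cycle list, 0 of 34 measured members were at least 2-fold higher and 13 lower (median log2 ratio −0.82, percentile 0), and of the WNT targets and stem cell genes 0 of 14 and 7 (−0.89, percentile 0.13). For interferon-stimulated genes, 20 of 37 measured members were at least 2-fold higher and 2 lower (median log2 ratio 1.04, percentile 100.0).

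In shMLKL cells after 12 h of TBZ, interferon-stimulated genes stood highest. CXCL10 went from 1.80 to 446 FPKM, the guanylate-binding protein gene GBP4 from 0.531 to 69.9 and CXCL11 from 1.60 to 95.3. IFIH1 went from 22.0 to 292, TNFSF10 from 14.9 to 216 and XAF1 from 3.59 to 52.0. Among the lowest ratios were those of the annexin ANXA13 (21.8 to 0.563) and the urea transporter SLC14A1 (15.8 to 0.414). CXCL8 stood at 1.06 and 42.9 FPKM and ICAM1 at 4.09 and 44.7. Of 10391 genes, 2138 differed at least 2-fold, 987 higher and 1151 lower, around a median log2 ratio of −0.14. For interferon-stimulated genes, 33 of 38 measured members were at least 2-fold higher and 1 lower (median log2 ratio 2.45, percentile 100.0). For the NF-kB list, 20 of 28 measured members were at least 2-fold higher and 0 lower (median log2 ratio 1.43, percentile 100.0). For the AP-1 and immediate early list, 5 of 24 measured members were at least 2-fold higher and 0 lower (median log2 ratio 0.58, percentile 100.0). In the cell cycle list, 0 of 33 were at least 2-fold higher and 9 lower (median log2 ratio −0.54, percentile 0.12), and of the ribosomal proteins 0 of 29 and 2 (−0.34, percentile 0.1). Replication-dependent histones, a sign of poly-A selection, had a median log2 ratio of 0.902 at 12 h (percentile 99.84) and of 0.779 at 4 h in parental cells (percentile 99.81), with 2 of 9 measured members at least 2-fold higher and 1 lower in each. The time and the line both differ from the 4 h comparison.

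Between shMLKL and parental cells under DMSO, SRSF3, a splicing factor, stood at 94.8 and 13.6 FPKM in parental and shMLKL cells, the ribosomal protein gene RPS20 at 1007 and 158 and LOC101927830 at 7.12 and 0.300, the lowest ratios. The endosomal GTPase RAB5B stood at 2.85 and 24.7, the Golgi protein TGOLN2 at 16.8 and 111 and CTH, of cysteine synthesis, at 3.66 and 27.3. Of the 10 genes named for shMLKL against shGFP under DMSO by size of change, 6 differed the other way here and 3 the same way. CFTR stood at 6.51 and 10.1, GABRP at 2.82 and 3.76, SCEL at 18.3 and 8.36, AKAP12 at 1.89 and 0.228, ALDH3A1 at 10.3 and 12.4 and C3orf52 at 8.27 and 3.83. The same way went PPP1R1B at 8.44 and 8.10, ALCAM at 0.978 and 1.55 and HSPA13 at 9.43 and 16.1, while IFI44L was listed at 1.35 and 0 and was not counted. In the MAP kinase feedback list, 0 of 14 measured members were at least 2-fold higher and 4 lower (median log2 ratio −0.71, percentile 0). In the AP-1 and immediate early list, 0 of 25 were at least 2-fold higher and 3 lower (median log2 ratio −0.31, percentile 0.1), opposite to its direction against shGFP cells. For ribosomal proteins 1 of 29 was higher and 0 lower (median log2 ratio −0.271, percentile 0.63), and for NF-kB targets 0 of 25 were higher and 3 lower (−0.188, percentile 2.07). BCL2 and caspase regulators lay at percentile 97.54 (1 of 24 higher and 1 lower, median log2 ratio 0.297). Of 10356 genes, 1406 differed at least 2-fold, 735 higher and 671 lower, around a median log2 ratio of 0.07. Extreme ratios that rest on a value of 0 were left out of these 3 comparisons (ARPC1B, SNORD41, MGAT4B, SQSTM1 and SNORD36A at 4 h; PPDPF, NDUFA3, HNRNPA1P10, SNORD44, ATP5MF and RPL34 at 12 h; RPL34, SNORD41, RPL10, SNCG, SQSTM1 and HNRNPA1P10 between the lines). At 4 h, at 12 h and between the lines, 368, 393 and 332 genes were listed at 0 in 1 library and at 5 FPKM or more in the other.

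The experiments were set side by side across genes, which are not independent replicates. The 4 h change in parental cells and the 5 h change in shGFP cells correlated with a Spearman rho of 0.595 and a Pearson r of 0.536 over 9281 genes, and 84.4% of the 5292 genes called in shGFP had the same sign at 4 h. The 12 h and 5 h changes in shMLKL cells correlated at 0.277 and 0.280 over 9325 genes, with the same sign in 67.1% of 3597 called genes. The difference between shMLKL cells and the control line under DMSO, a pair added after the data were seen, correlated at −0.158 and −0.105 over 9312 genes, with the same sign in 39.4% of 5984 called genes. The control line was parental in the first experiment and shGFP in the second.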

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

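Of the tests below, those of the authors' normalization, of depth and of the level before TBZ were chosen only after the results were seen; those of the knockdown and of failed estimates were set before. The results gathered here are TBZ effects that differed between the shMLKL and shGFP lines by the test of the difference itself (limma or camera, BH), and transcripts of the first experiment that no comparison uses. In all, 2306 genes, 15 lists and 77 reported named genes met the first condition. A further 12 named genes did so but were listed at 0 in a library, and no fold is given for them in this section. The 2-fold threshold was not applied to them. Of the 77, 57 kept their call in every other alternative and 20 lost it in at least 1: ALCAM, ANXA1, BUB1B, C9orf152, ERN1, FGF19, GABRP, GBP2, HIST1H2BC, HIST1H2BL, IFI44L, IFIH1, KRT19, MLKL, MYC, NFKBIA, PI3, SLITRK6, TNFAIP3 and TRAF2.

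The mean log2 differences of the lists, shMLKL minus shGFP, were negative for AP-1 and immediate early genes (−1.48), MAP kinase feedback regulators (−1.10), cytokines and growth factors (−0.87), intestinal differentiation (−0.63, or −0.132 without genes listed at 0), chemokines (−0.52), cholesterol genes (−0.51), p53 targets (−0.41), NF-kB targets (−0.40), heat shock and oxidative stress (−0.25), the unfolded protein and integrated stress response (−0.22), glycolysis and hypoxia (−0.14) and BCL2 and caspase regulators (−0.14) and positive for cell cycle (0.41), interferon-stimulated genes (0.32) and the TRIM28 corepressor complex (0.23). With an estimated correlation 5 of these 15 kept their call. The chemokine call was lost with library medians set equal (camera BH-adjusted p = 0.0537) and the glycolysis call after quantile normalization (0.369).

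The named genes with differences of −2 or less on the log2 scale were GEM (−3.43), DUSP1 (−3.34), RHOB (−3.20), NR4A1 (−3.18), AKAP12 (−3.12), CXCL8 (−2.98), CSF2 (−2.82), HBEGF (−2.73), INSIG1 (−2.57), THBS1 (−2.56), ATF3 (−2.35), DKK1 (−2.33), CXCL1 (−2.18), JUN (−2.17), DUSP5 (−2.13), HMGCS1 (−2.10) and ERRFI1 (−2.08). Between −1 and −2 lay CCL20 (−1.95), EGR1 (−1.89), C3orf52 (−1.81), PI3 (−1.74), IER3 (−1.73), PPP1R15A (−1.69), CDKN1A (−1.57), KRT20 (−1.54), FOSL1 (−1.51), GBP1 (−1.46), MCL1 (−1.39), PMAIP1 (−1.26), BTG2 (−1.21), ISG20 (−1.18) and HIST1H2BC (−1.0). Smaller negative differences were those of GCLC (−0.94), ADM (−0.94), PFKFB3 (−0.93), IDI1 (−0.91), FGF19 (−0.90), MUC5AC (−0.90), TXNRD1 (−0.89), STARD4 (−0.81), DUSP10 (−0.78), DUSP4 (−0.67), GBP2 (−0.63), CFLAR (−0.60), BBC3 (−0.59), SLC2A1 (−0.55), TNFAIP3 (−0.52), ANXA5 (−0.48), ALCAM (−0.47), ERN1 (−0.46), SRXN1 (−0.44), DNAJA1 (−0.31), ANXA1 (−0.25), KRT19 (−0.22) and NFKBIA (−0.20). Positive differences were those of HOXA13 (2.02), GATA2 (1.65), SOSTDC1 (1.55), HIST1H2BL (1.41), CXCL10 (1.38), TNFSF10 (1.10), XAF1 (1.08), AXIN2 (1.06), KIF20A (0.98), BMP4 (0.90), CFTR (0.90), GABRP (0.69), C9orf152 (0.68), SLITRK6 (0.68), MLKL (0.66), TRAF2 (0.65), IFI44L (0.54), BUB1B (0.37), IFIH1 (0.35), PLK1 (0.34), CBX3 (0.32) and MYC (0.22).

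The smaller rise of immediate early genes in shMLKL cells was weighed against 3 explanations. With library medians set equal, the median difference over the 27 measured members was −1.388, which argues against the authors' normalization as the cause. Over the 12 members with a mean of 20 FPKM or more it was −1.474, but the rise in shGFP itself lifts that mean. Estimated depth was 84.4 and 82.9% in shMLKL TBZ and 96.2 and 95.5% in shGFP TBZ. That gap is too small for a median log2 difference of −1.031 under TBZ, which argues against lower depth as the cause. A higher level in shMLKL cells before TBZ would leave the lines level under TBZ, but there shMLKL lay lower by the same median. The loss of MLKL, or of the membrane damage it causes, may underlie the difference, but line-specific effects other than MLKL were not tested and stay open, since 1 shRNA line was compared with 1 control line.

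The shMLKL and shGFP lines differed at 6539 genes before any TBZ. With library medians set equal 5871 genes were called, so a shift of library medians is not the whole cause, though setting them equal moves the direction of many calls. If the knockdown caused most of the differences, genes at least 2-fold apart should differ the same way from parental cells in the first experiment. 105 of 329 did (31.9%), so the prediction failed. Genes are not independent and each line there was a single library, so knockdown is not ruled out. Differences between the lines that arose in culture or selection could remain, as could differences between the shGFP line and parental cells; no library tests either.

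Expressed genes listed at 0 in some libraries were weighed as failed estimates. Of the 79 such genes that reached 5 FPKM in another library and were matched in the first experiment, 30, or 38.0%, stood at 1 FPKM or more in all 4 of its libraries. This lies between the set limits, 50 and 25%, and that experiment's lists hold zeros of the same kind, so the test cannot decide. Replicates of a group split for some genes: EIF2S2 had 150.6 and 0 FPKM in shGFP DMSO, and TAX1BP1 0 and 96.5 in shMLKL TBZ. This argues against absent expression for such genes. Genes at 0 in both replicates stay open. No biological explanation was tested.

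Among transcripts assembled by Cufflinks outside annotated genes, 1 on chromosome 3 (98699903 to 98717680, forward strand) stood at 45.1 FPKM (deposited interval 42.5 to 47.7) in shMLKL cells after 12 h of TBZ, against 2.4 for overlapping transcripts under DMSO. Another, on chromosome X (13397213 to 13397504, reverse strand), stood at 28.83 FPKM (15.58 to 42.07) in parental cells after 4 h, against 8.56, but at this place 30.4 FPKM (18.43 to 42.37) stood against 26.59 in shMLKL cells after 12 h. They were picked as those at 20 FPKM or more and over 3 times the control, limits set after the data were seen, and each value rests on a single library.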

How the results depend on the processing

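The alternatives added after the data were seen are named with the methods, and the others were planned. Counts of called genes stayed within 1.5 times the reported count under both pseudocounts, both filters, quantile normalization, equal medians, the replicate block (5711, 3714, 2062, 6450 and 5222 genes in the order of the contrasts), no trend and robust empirical Bayes. By construction, a 2-fold threshold left fewer: 537, 296, 195, 414 and 276. Leaving out 1 library, with the lone sample of its group assumed to vary like the other groups, gave 4576 to 5837, 2846 to 3680, 1314 to 1690, 5490 to 6562 and 4181 to 5264. The difference of effects fell by over 1.5 times without shGFP DMSO 1 (1314), DMSO 2 (1452), TBZ 1 (1466), TBZ 2 (1417) and shMLKL DMSO 2 (1478), where fewer samples are fitted. Scaling moved the balance of directions. Calls higher in shMLKL under DMSO made up 29% as deposited and 53.1% with medians equal, and positive differences of effects 65.6 and 38.9%. Equal medians also remove real shifts, so the cause is open. Since the files hold no counts, the alternatives for count data were not run.

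Calls of lists depended most on the setting of camera: with an estimated correlation 7 lists were called for TBZ in shGFP, 1 in shMLKL, 5 for the difference of effects, and 0 for shMLKL against shGFP under DMSO and 0 under TBZ, where camera at the preset value called 14, 12, 15, 12 and 7. By construction this setting also tests with the 4 residual degrees of freedom of the fit. Fry called 16 under TBZ; the cause was not tested. Fry also gave the opposite sign to camera, which sets a list against other genes, for kidney and liver markers with TBZ in shMLKL (0.216, fry BH-adjusted p = 0.00590), BCL2 and caspase regulators under DMSO (−0.101, 0.0179) and glycolysis under DMSO (−0.005, 0.00519). Leaving out 1 library gave 14 to 14, 12 to 13, 14 to 16, 10 to 14 and 5 to 8 called lists. Equal medians changed the calls of 4 of 110 list and contrast pairs and quantile normalization those of 10; in no called list did either turn the direction. The histone call under DMSO was lost under both (camera BH-adjusted p = 0.158 and 0.0754) and the ESCRT-III call after quantile normalization (0.135).

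Over 630 pairs of a named gene and a contrast, quantile normalization ended 22 calls and added 12, equal medians 20 and 17, and a pseudocount of 0.1 ended 12 and added 7; leaving out a library ended between 19 and 30. Directions reversed for IL17C in the difference of effects with a pseudocount of 0.1 (0.066, limma BH-adjusted p = 0.900; it is listed at 0 in both shMLKL DMSO libraries), for IER3 under DMSO with equal medians (0.154, 0.0129) and for INSIG1 under DMSO after quantile normalization (0.009, 0.920); the cause was not tested. The MLKL difference of effects was not called with a pseudocount of 0.1 (0.787, adjusted p = 0.0905, limma), where low values spread more, or without shGFP DMSO 1 (0.648, 0.0503), and ranged from 0.536 to 0.779 over the libraries left out; its other 4 contrasts kept their side of the threshold.

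In the first experiment a pseudocount of 5 left 1047, 1007 and 608 genes at least 2-fold apart, since it shrinks ratios of low genes; between shMLKL and parental cells a filter of 5 FPKM left 915 of the 1406, where fewer genes are counted, and adding assembled transcripts 848 (the cause was not tested). The correlation across genes of the 4 h and 5 h changes was 0.700 and that of the 12 h and 5 h changes 0.443 over called genes alone. The correlation of the TBZ effects of the lines was 0.730 over called genes and 0.648 over all genes with a pseudocount of 0.1, and 0.664 over all genes without those listed at 0; the cause was not tested.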

Other observations

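Glycolysis and hypoxia genes went both ways with TBZ. In shGFP cells 5 of 21 measured members rose and 7 fell, and in shMLKL cells 3 and 4 (camera BH-adjusted p = 0.774 and 0.327). ADM, the vasodilator adrenomedullin, rose from 1.15 ± 0.0821 to 7.64 ± 0.901 FPKM in shGFP and from 2.23 ± 0.434 to 5.72 ± 0.377 FPKM in shMLKL cells, and the glycolytic regulator PFKFB3 from 2.53 ± 0.324 to 10.3 ± 0.108 FPKM and from 1.75 ± 0.134 to 3.64 ± 0.110 FPKM. The glucose transporter SLC2A1 fell from 59.5 ± 3.26 to 36.7 ± 0.179 FPKM and from 76.4 ± 2.02 to 32.0 ± 0.0781 FPKM. Of 18 intestinal differentiation genes 2 rose and 9 fell in shGFP, and 2 and 9 in shMLKL cells (camera BH-adjusted p = 0.613 and 0.00219, the latter 0.135 with an estimated correlation). The mucin MUC5AC rose from 3.38 ± 0.0537 to 14.8 ± 1.24 FPKM in shGFP and from 3.14 ± 0.278 to 6.99 ± 0.201 FPKM in shMLKL, and the goblet cell factor SPDEF fell from 6.14 ± 0.657 to 1.97 ± 0.177 FPKM and from 3.77 ± 0.00206 to 1.35 ± 0.0107 FPKM. KRT20 rose from 87.7 ± 2.27 to 209 ± 0.143 FPKM in shGFP and fell from 231 ± 3.00 to 188 ± 0.238 FPKM in shMLKL cells, while KRT19 fell in both, from 147 ± 3.14 to 95.9 ± 4.61 FPKM and from 185 ± 0.803 to 103 ± 1.65 FPKM. The keratins KRT8 and KRT18, abundant in this line, were listed at 0 in 7 libraries and at 694 and 535 FPKM in shMLKL DMSO 2. Without genes listed at 0 the list mean in shMLKL was −0.222 (camera BH-adjusted p = 0.00301).

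Membrane repair genes split as well. Of 27 ESCRT-III and repair genes 7 rose and 7 fell in shGFP, and 5 and 3 in shMLKL cells (camera BH-adjusted p = 0.262 and 0.746). The phosphatidylserine-binding annexin ANXA5 rose from 231 ± 2.21 to 398 ± 9.24 FPKM and from 387 ± 14 to 478 ± 6.39 FPKM, and ANXA1 fell from 303 ± 6.88 to 275 ± 4.94 FPKM and from 571 ± 35.6 to 436 ± 0.435 FPKM, a fall that in shGFP was not called with library medians set equal (−0.07, limma BH-adjusted p = 0.238). FLOT1, of lipid rafts, fell from 5.92 ± 0.0969 to 3.70 ± 0.247 FPKM in shGFP and from 6.19 ± 0.427 to 5.05 ± 0.141 FPKM in shMLKL. There the call was lost without shMLKL DMSO 1, TBZ 1 or TBZ 2. Between the lines under DMSO, 10 of the list were higher and 8 lower in shMLKL (camera BH-adjusted p = 0.0421, 0.243 with an estimated correlation). Ribosomal protein genes shifted little with TBZ (list mean −0.06 in shGFP and 0.00 in shMLKL, camera BH-adjusted p = 0.612 and 0.985), and the size of the shift depended on the scaling: in shGFP the mean was −0.115 after quantile normalization, where the list was called (camera BH-adjusted p = 0.00618), and 0.004 with library medians set equal. Replication-dependent histones, a sign of poly-A selection, gave 2 rises and 3 falls of 17 in shGFP and 1 and 2 in shMLKL (camera BH-adjusted p = 0.811 and 0.251). Of the leukocyte and of the kidney and liver markers 3 each were measured, and neither list was called in any contrast (lowest camera BH-adjusted p = 0.395 and 0.0945).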
